A study of Homo sapiens with 20 samples.

How the data were processed

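RNA abundance was measured on one-colour oligonucleotide microarrays made by Agilent, in the human lens epithelial cell line HLE-B3. The 20 arrays fell into 3 lines by their labels: parental cells (n = 8), cells labelled as overexpressing αA-crystallin (n = 8) and cells labelled as overexpressing αB-crystallin (n = 4). Per the labels, every culture had received dexamethasone at 0.1, 1, 10 or 100 μmol for 36 or 48 h. The labels give no volume for these amounts, so they are used as labelled dose. The parental and αA-labelled lines had 1 array at each of 8 combinations of dose and time, and the αB-labelled line had 1 array at each of 4 (10 and 100 at both times). No combination was repeated within a line and no untreated culture was among the samples. The word pair is used for arrays of 2 lines or 2 times at the same labelled dose, which are not otherwise linked.

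Per the file headers, the deposited intensity values of each array came from Agilent Feature Extraction 10.7.1.1. The processed signal is an intensity that this program had background-subtracted, detrended across the array and replaced by a small surrogate where a spot was too dim. It had not been normalised between arrays. The same deposited files give the mean intensity of each spot and the median of its local background. The deposited summary table holds log2 values, per the file headers with no named method. All 58341 sorted values of its 20 columns were identical between columns within 1e-06, which is what quantile normalisation gives, and each column correlated with log2 of the processed signal of its own array (r between 0.989 and 1.000 across probes).

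Spots that the program marked as outliers were left out (3138 over all arrays) and replicate spots were averaged, which gave 58201 probes. The log2 processed signal minus the 75th percentile of its array was used throughout and is called normalised log2 signal. Accessions in the files were matched to current gene names for 31104 probes, 22224 kept the name in the file, and 1507 had no gene name. Each gene was represented by its probe with the highest mean over the 20 arrays. Features called well above background by the program on at least 4 arrays were tested, 30505 of 43579, of which 15846 were protein-coding genes and 6234 carried a name used for long noncoding RNAs. Probe positions are those in the files, on hg19. For arrays, the number of arrays and the signal over background limit the precision. Where a probe was below background on all arrays of a line, a fold against that line is given as "at least", computed against the lowest signal called above background on each array. XIST and Y-linked genes were not named (71 features).

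Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Line, time and log10 of the labelled dose were additive terms fitted to all 20 arrays, which left 15 residual degrees of freedom. The spread against which a difference was judged was therefore what these terms left over, not a spread between repeated cultures, and every p-value measures only the spread between these samples. The 5 comparisons were αA-labelled against parental, αB-labelled against parental, αA-labelled against αB-labelled, 48 h against 36 h, and the slope per 10-fold dose. Line by time and line by dose terms were added to test whether effects differed between lines. Errors of log2 differences are standard errors (SE) of the fit. Single probes for CRYAA, CRYAB and transcripts named lnc-TMPRSS15 were also compared between pairs by exact two-sided tests: sign flips over 8 pairs for the αA-labelled line and permutation of 4 against 4 arrays for the αB-labelled line.

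Lists of 22 gene groups (glucocorticoid-induced genes, glucocorticoid-repressed inflammatory genes, crystallins, lens fibre and lens epithelium genes, heat shock proteins and chaperones, unfolded protein response, NRF2 antioxidant genes, p53 targets and apoptosis, epithelial-mesenchymal transition and fibrosis, cell cycle, type I interferon response, cholesterol biosynthesis, glycolysis and hypoxia, immediate early genes, well-known long noncoding RNAs, and markers of fibroblasts, retinal pigment epithelium, keratinised epithelium, endothelium, leukocytes and neurons) were tested with camera at a preset correlation of 0.01, adjusted over 110 tests. The camera test was repeated with an estimated correlation. Of 514 list entries, 511 had a probe. The genes named were set by a rule: for each of the 5 comparisons, the 6 largest rises and 6 largest falls that passed the threshold, went the same way in every pair and were above background on every array of at least 1 group; likewise 3 and 3 long noncoding RNAs; up to 2 risen and 2 fallen members of each called list; and always CRYAA, CRYAB, NR3C1, FKBP5, TSC22D3, PER1, ZBTB16 and features named lnc-TMPRSS15. For dose, the slope had to keep its sign in all 6 series of 1 line and 1 time. These choices, the 22 lists and most alternatives were fixed before the data were examined.

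The file headers place the arrays on 4 slides. Slide 1 held 2 αA-labelled arrays, slide 2 held 6 αA-labelled and 2 αB-labelled arrays, slide 3 held 2 αB-labelled and 6 parental arrays, and slide 4 held 2 parental arrays. The αA-labelled and parental lines never shared a slide. The αB-labelled arrays at 36 h were on slide 2 and those at 48 h on slide 3, so that for this line time and slide cannot be told apart. Alternatives were slide as a fixed or random block, quantile normalisation, normexp correction (offset 50) with quantile normalisation, centring on the array median, the deposited log2 table, no filter, a filter on all 20 arrays, the mean over probes, array weights, matched conditions only, single times, dose as a factor, and leaving out each array in turn. Fits without slide 1, without slide 1 and 1 further array, and on slide 2 or slide 3 alone were added after the data had been seen, as were 14 gene families, a list of fatty acid oxidation genes and the examples of interactions.

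The fit was tested on simulated arrays in which, among 30505 genes, 67 were changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. For the αA-labelled against the parental line it recovered 44.8%, 91.0% and 98.5% of these. For the αB-labelled against the parental line these shares were 38.8%, 76.1% and 97.0%, for the αA-labelled against the αB-labelled line 38.8%, 70.1% and 95.5%, and for time 58.2%, 88.1% and 98.5%. For dose slopes it recovered 91.0% of the changes of 0.5 and 100% of the larger ones. Unchanged genes made up 3.11% of the calls for the αA-labelled and 4.73% for the αB-labelled against the parental line, 4.90% between the labelled lines, 7.39% for time and 4.90% for dose. For the αA-labelled against the parental line, camera found a raised list of 25 genes to be higher and called 2 of 100 unchanged lists. The simulated noise was independent between genes and held no slide effect. These shares therefore say nothing about false calls from correlated genes or from slides. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3 for reading the files.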

Results

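Gene expression was measured in HLE-B3 cells, an established virus-transformed line of human lens epithelium, after treatment with dexamethasone, a synthetic glucocorticoid. The arrays comprised 8 of parental cells, 8 of cells labelled as overexpressing αA-crystallin and 4 of cells labelled as overexpressing αB-crystallin. αA- and αB-crystallin, encoded by CRYAA and CRYAB, are small heat shock proteins that keep other lens proteins soluble. The 75th percentile of the processed signal lay between 323.9 and 507.7 per array. Between 34145 and 38353 probes were above background on 19 arrays, and 48295 were on the αA-labelled array at 48 h and 0.1 μmol. The series title names a long noncoding RNA, lnc-TMPRSS15, and the labels imply comparisons of lines, times and doses. No combination of line, time and dose had a second array, so no single combination has a replicate check.

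CRYAA and CRYAB were examined first, because the labels say that one or the other was overexpressed. CRYAA signal was high in the αB-labelled arrays and not in the αA-labelled arrays. At probe A_23_P132147 (chromosome 21, 44590682 to 44590741, hg19) the normalised log2 signal was -0.24 ± 0.14 (SD, n = 4) in the αB-labelled line. At this probe the other lines lay at -7.64 ± 0.20 (SD, n = 8) in parental cells and -7.51 ± 0.83 (SD, n = 8) in αA-labelled cells, above background on 0 and 1 arrays. Signal was thus at least 35.1-fold higher in the αB-labelled than in the parental line, and higher in 4 of 4 pairs (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give). At the second CRYAA probe, A_33_P3323559, the αB-labelled line exceeded the parental line by 1.20 ± 0.25 (SE) on the log2 scale. The αA-labelled line differed from the parental line there by -0.29 ± 0.19 (higher in 2 of 8 pairs, exact two-sided sign-flip p = 0.227). This pools arrays that stood apart by slide. The αA-labelled arrays averaged 0.02 on slide 1 and -1.25 on slide 2, against -0.71 and -0.41 for parental arrays on slides 3 and 4. Another CRYAA probe, A_33_P3253006, was above background on 2 arrays, both αA-labelled.

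CRYAB signal was highest in the αA-labelled arrays. At its single probe (A_24_P206776, chromosome 11, 111779576 to 111779635) the αA-labelled line exceeded the parental line by 0.60 ± 0.05 (SE), in 8 of 8 pairs (exact two-sided sign-flip p = 0.00781, the smallest that 8 pairs can give). The αB-labelled line exceeded it by 0.20 ± 0.07, in 4 of 4 pairs (adjusted p = 0.0907 over all probes and 0.0405 over the features above background). Blocked by slide, the CRYAB difference of the αA-labelled line was 0.54 ± 0.13 (adjusted p = 0.053 over all probes and 0.0151 over the features above background) and the CRYAA difference of the αB-labelled line at A_33_P3323559 was 1.41. The CRYAB difference of the αB-labelled line was then 0.15 (adjusted p = 0.564 over all probes and 0.332 over the features above background), so its call was lost. Within slide 2 the αA-labelled minus αB-labelled difference was -1.59 for CRYAA at A_33_P3323559 (adjusted p = 0.00175 over the features above background). For CRYAB it was 0.38 (adjusted p = 0.0874 over these features and 0.226 over all probes). CRYAA therefore went against the labels. CRYAB was highest in the line not labelled for it, but by a small difference, and was also slightly higher in the αB-labelled line than in parental cells. The lines are called αA-labelled and αB-labelled throughout. Every direction given for a line is that of the arrays so labelled.

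**Figure D1:**
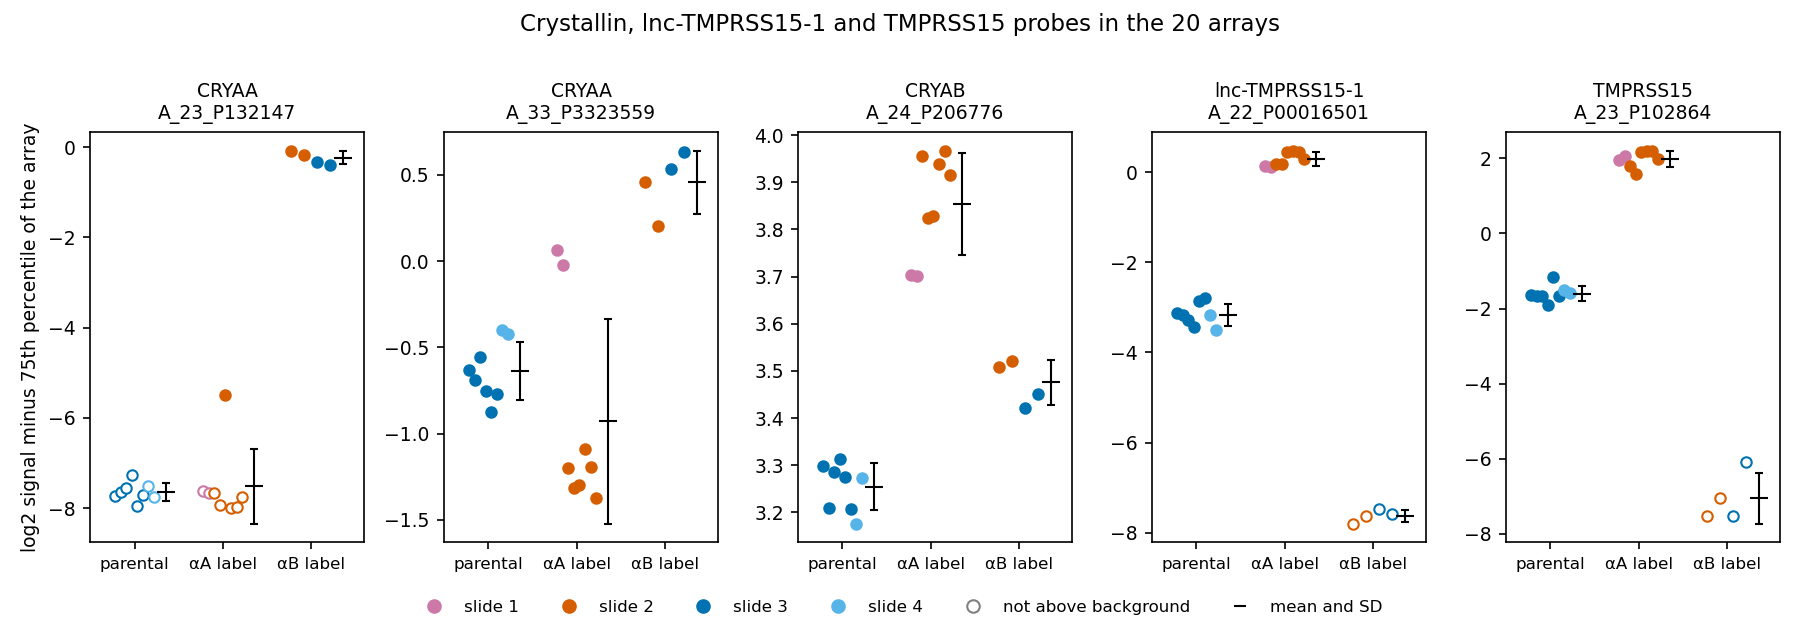
Normalised log2 signal (y axis, log2 of the processed signal minus the 75th percentile of its array) of 5 probes in the 20 arrays, by line (x axis) and coloured by slide, with the mean and SD beside each group and open symbols for arrays where the probe was not above background. CRYAA at A_23_P132147 lies near -0.24 in the 4 αB-labelled arrays and at or below -5.48 in the others, and lnc-TMPRSS15-1 and TMPRSS15 are highest in the αA-labelled and lowest in the αB-labelled arrays.

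The series title names lnc-TMPRSS15, and 1 probe of lnc-TMPRSS15-1 separated the 3 lines. lnc-TMPRSS15-1 (A_22_P00016501, chromosome 21, 19849676 to 19849735) had a normalised log2 signal of 0.29 ± 0.15 (SD, n = 8) in the αA-labelled line and -3.17 ± 0.25 (SD, n = 8) in parental cells. It was below background on all 4 αB-labelled arrays. The αA-labelled line exceeded the parental line by 3.45 ± 0.07 (SE), a fold of 10.9, in 8 of 8 pairs (limma adjusted p = 4.07e-15). Signal in the αB-labelled line was at least 4.61-fold lower than in parental cells and at least 50.5-fold lower than in the αA-labelled line. The difference of the αA-labelled line from parental cells was 3.32 with slide as a block. The neighbouring gene TMPRSS15, which encodes the intestinal protease enteropeptidase, followed the same order, with a log2 difference of 3.59 ± 0.15 in the αA-labelled line and signal at least 13.7-fold lower in the αB-labelled line than in parental cells. A second probe for lnc-TMPRSS15-1 and the probes for lnc-TMPRSS15-4, lnc-TMPRSS15-5, lnc-TMPRSS15-9, lnc-TMPRSS15-10 and lnc-TMPRSS15-14 (LINC01687) were below background on every array. Those for lnc-TMPRSS15-7 and lnc-TMPRSS15-8 were above background on 1 αA-labelled array each. The probe for lnc-TMPRSS15-13 was above background on 6 parental, 6 αA-labelled and 4 αB-labelled arrays. It did not pass the adjusted threshold for any pair of lines. Other probes that carry the name, for lnc-TMPRSS15-2, lnc-TMPRSS15-11 and lnc-TMPRSS15-12 (LINC00317), were above background on all 20 arrays and did not pass the adjusted threshold for any pair of lines. Their log2 differences from parental cells were 0.09, -0.16 and -0.16 in the αA-labelled and 0.10, -0.15 and -0.31 in the αB-labelled line. With slide as a block they were 1.31, 0.10 and -0.41 in the αA-labelled and 0.98, 0.19 and -0.33 in the αB-labelled line. None passed there either, so the sizes for lnc-TMPRSS15-2 and the signs for lnc-TMPRSS15-11 depended on how slide was treated. LINC00317 was lower in 4 of 4 αB-labelled pairs (exact two-sided permutation p = 0.0286 for this probe alone). Neither time nor dose passed the threshold for lnc-TMPRSS15-1, with a log2 difference of 0.21 (adjusted p = 0.054) and a slope of -0.09 per 10-fold dose (adjusted p = 0.167).

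The αA-labelled line was compared with parental cells, a comparison that asks how the 2 lines differ under the same treatment. The αA-labelled line expressed genes that were not detected in parental cells: signal of SH3GL2, which encodes the endocytic protein endophilin A1, was at least 29.3-fold higher, and that of PENK-AS1, antisense to the enkephalin precursor gene, was at least 48.5-fold higher. LMO3, a LIM-only transcription cofactor, was higher by 4.68 ± 0.14 (SE). The testis-associated gene MNS1 was lower by 2.98 on the log2 scale (-2.98 ± 0.08) and the pseudogene CDRT15P2 was at -3.33 ± 0.13, both in 8 of 8 pairs. Many genes of inflammation, interferon response and connective tissue were lower.

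Of 27 measured inflammatory genes that glucocorticoids repress, 22 were lower and 1 was higher in the αA-labelled line (23 and 1 adjusted over the list alone). The chemokine CCL2 differed by -2.55 ± 0.12, TNFAIP6 by -2.35 ± 0.11, and the one higher gene, IL11, by 0.40 ± 0.09. The list median was -0.90, or -0.88 with 2 members below background in a line set at their bound (camera adjusted p = 3.93e-12, and adjusted p = 0.146 with an estimated correlation). Of 30 type I interferon response genes, 20 were lower and 2 were higher (20 and 3 adjusted over the list alone). BST2, a membrane protein that tethers budding virus, differed by -2.02 ± 0.09 and OAS3 by -1.15 ± 0.06, while HERC6 differed by 0.62 ± 0.13. The interferon list median was -0.57 (camera adjusted p = 3.81e-09, and adjusted p = 0.054 with an estimated correlation). Of 15 fibroblast markers, 11 were lower and 1 was higher (11 and 2 adjusted over the list alone), among them PRRX1 at -1.38 ± 0.09 and FAP at -1.02 ± 0.07 (camera adjusted p = 3.89e-05, and adjusted p = 0.146 with an estimated correlation). Of 30 genes of epithelial-mesenchymal transition and fibrosis, 16 were lower and 4 were higher (18 and 5 adjusted over the list alone). The matrix protein gene TNC differed by -2.65 ± 0.12 and the cadherin gene CDH11 by 0.73 ± 0.07 (camera adjusted p = 0.00476, and adjusted p = 0.639 with an estimated correlation). The medians of these 4 lists were -0.83, -0.60, -0.70 and -0.30 with slide as a block, with adjusted p between 4.17e-09 and 0.000295.

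In all, 10170 of 30505 features differed between the αA-labelled and parental lines, 4489 higher and 5681 lower, of which 6224 went the same way in all 8 pairs and 1111 differed by at least 1 on the log2 scale. The 2 lines shared no slide, so no within-slide value can be had and they are linked only through the αB-labelled arrays. Blocked values of this comparison therefore assume that the αB-labelled line had the same time effect as the other lines. Its time effect was called different for 828 features, which cannot be told apart from slide. With the block, the median of 22 amino acid synthesis and transfer RNA synthetase genes went from 0.07 to 0.77. Blocked by slide, 1267 features passed the threshold, 1146 of them among the 10170 and in the same direction. Of the 10170, 8808 (86.6%) kept their sign, the median SE rose from 0.0812 to 0.208 and the sizes changed by a median factor of 0.806. Among the genes named above, IL11 (0.02 with slide as a block, adjusted p = 0.979), CDH11 (0.62, adjusted p = 0.155), FAP (-0.78, adjusted p = 0.0547) and HERC6 (1.29, adjusted p = 0.0646) no longer passed the threshold with slide as a block. The same held for HSD11B1, which encodes the enzyme that regenerates cortisol, at -3.63 ± 0.25 without and -2.52 with the block (adjusted p = 0.0607). PARM1 (4.11 without and 2.25 with the block, adjusted p = 0.11) and CXCL6 (-3.26 and -3.15, 0.095) were lost too. So were ZNF681 (-2.78 and -2.51, 0.221) and LINC02182 (-2.06 and -0.75, 0.747). Of 33 features given by the naming rule and called here, 31 kept their sign and 19 also passed with the block.

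The αB-labelled line was compared with parental cells in the same way. Several genes that parental cells expressed were below background in the αB-labelled line. Signal of HOXA3, a homeobox transcription factor gene, was at least 18.2-fold lower, that of PLXDC2 at least 16.6-fold lower and that of LINC01419 at least 28.3-fold lower. TLL1, which encodes a tolloid-like metalloprotease, was higher by 5.43 ± 0.18 (SE), a fold of 43.0, in 4 of 4 pairs. GAGE7, a cancer-testis gene, was at least 9.71-fold higher. Of the 1133 features that differed by at least 1 on the log2 scale, 941 were lower and 192 were higher.

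Many inflammatory, interferon and connective tissue genes were lower in the αB-labelled line too. Both comparisons use the same parental arrays, so this likeness is not independent. Of 27 glucocorticoid-repressed inflammatory genes 18 were lower and 0 were higher (20 and 0 adjusted over the list alone), with CCL2 at -4.44 ± 0.15 and TNFAIP6 at -3.34 ± 0.14. Their median was -0.70, or -0.57 with 4 members at their bound (camera adjusted p = 6.59e-12, and adjusted p = 0.146 with an estimated correlation). Of 15 fibroblast markers 10 were lower and 0 were higher (11 and 0 adjusted over the list alone), with the small proteoglycans LUM at -2.40 ± 0.10 and DCN at -2.15 ± 0.13. The fibroblast median was -0.70, or -0.62 with 2 members at their bound (camera adjusted p = 1.7e-10, and adjusted p = 0.0533 with an estimated correlation). Of 30 interferon response genes 15 were lower and 0 were higher (16 and 0 adjusted over the list alone), with IFIH1 at -1.28 ± 0.08 (camera adjusted p = 2.8e-07, and adjusted p = 0.0927 with an estimated correlation). Of 30 epithelial-mesenchymal transition genes 15 were lower and 1 was higher (16 and 2 adjusted over the list alone), with CDH11 at -2.88 ± 0.10 and the gelatinase gene MMP2 at -2.18 ± 0.13 (camera adjusted p = 7.35e-07, and adjusted p = 0.415 with an estimated correlation). Of 10 leukocyte markers 2 were lower, CD14 at -1.15 ± 0.11 and LCP1, whose signal was at least 3.02-fold lower (camera adjusted p = 0.0453, and adjusted p = 0.195 with an estimated correlation).

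Some cell cycle and antioxidant genes were higher. Of 33 cell cycle genes 7 were higher and 0 were lower (8 and 0 adjusted over the list alone), with the cyclin gene CCNE1 at 1.02 ± 0.06, although 1 of its 4 αB-labelled arrays lay apart at 2.50 against 2.63 to 2.65 (camera adjusted p = 9.24e-06, and adjusted p = 0.54 with an estimated correlation). Of 20 genes controlled by the oxidant-responsive factor NRF2, 7 were higher and 0 were lower (8 and 1 adjusted over the list alone), with AKR1C1 at 1.18 ± 0.11 and NQO1 at 0.61 ± 0.10 (camera adjusted p = 0.000826, and adjusted p = 0.397 with an estimated correlation). The 7 lists kept their direction with slide as a block, with adjusted p between 2.68e-11 and 0.0446. In all, 5366 features differed between the αB-labelled and parental lines, 2417 higher and 2949 lower, and 5006 of these went the same way in 4 of 4 pairs. With slide as a block 2873 passed, 2607 of them shared and in the same direction, and the median size was 0.978 of that without the block. Within slide 3, which held 2 αB-labelled and 6 parental arrays, 1492 passed. There CCL2 differed by -4.03, TLL1 by 5.67 and the median inflammatory gene by -0.80. Centring on the array median gave 2912, a fit of the matched arrays with their 4 conditions as a block 2554 and the 48 h arrays alone 3237.

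**Figure D2:**
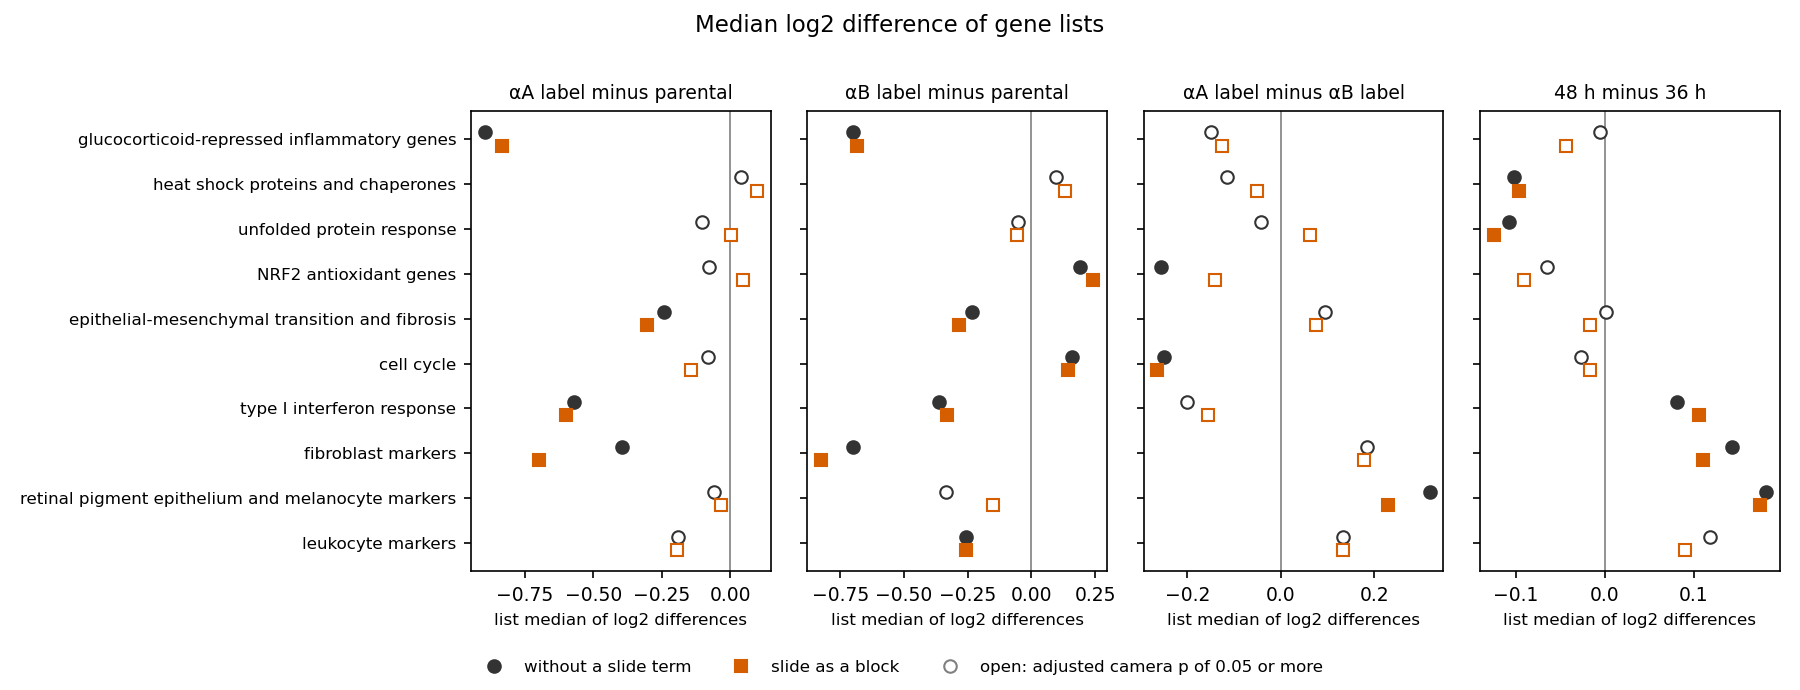
Median log2 difference (x axis) of the gene lists (y axis) called in at least 1 of 4 comparisons, without a slide term (circles) and with slide as a block (squares); filled symbols have a camera adjusted p under the threshold at the preset correlation. Inflammatory, interferon, fibroblast and epithelial-mesenchymal transition lists lie below 0 in both labelled lines against the same parental arrays, the inflammatory list at -0.90 and -0.70.

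The direct contrast of the labelled lines asks which genes separate them. The αA-labelled line had more signal of TMPRSS15 (at least 165-fold), LINC01419 (at least 121-fold), PLXDC2 (at least 72.2-fold) and LMO3 (at least 65.9-fold), all below background in the αB-labelled line. TLL1 was lower in the αA-labelled line, at -5.78 ± 0.18 (SE) in 4 of 4 pairs. The zinc finger gene ZNF681 was lower too, at -3.61 ± 0.40, but it was above background on 1 of 8 αA-labelled arrays, so this size is rough. Within slide 2 it was at -3.24 (limma adjusted p = 0.083). Of 33 cell cycle genes 17 were lower in the αA-labelled line and 0 were higher (18 and 0 adjusted over the list alone). Among them CCNE1 was at -1.39 ± 0.06 and NUSAP1, a spindle protein gene, was at -0.53 ± 0.08, although 1 αB-labelled array stood apart for each of these genes (camera adjusted p = 0.000183, and adjusted p = 0.587 with an estimated correlation). Of 20 NRF2 genes 8 were lower and 0 were higher (8 and 1 adjusted over the list alone), with NQO1 at -1.04 ± 0.10 (camera adjusted p = 0.0453, adjusted p = 0.587 with an estimated correlation, and adjusted p = 0.412 with slide as a block). Of 10 markers of retinal pigment epithelium and melanocytes 5 were higher and 0 were lower, with the chloride channel gene BEST1 at 2.30 ± 0.11 (camera adjusted p = 0.0129, and adjusted p = 0.195 with an estimated correlation).

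In all, 9692 features differed between the labelled lines, 4540 higher and 5152 lower in the αA-labelled line, and 8995 went the same way in 4 of 4 pairs. A slide term left 7702, 6719 of them shared and in the same direction, and the list medians for cell cycle and pigment genes were -0.26 and 0.23 (adjusted p = 0.000107 and 0.0269). Within slide 2, which held 6 αA-labelled and 2 αB-labelled arrays, 3647 passed, CCNE1 differed by -1.40 and the median cell cycle gene by -0.34. Centring on the array median shifted the median of all features by -0.170 in this contrast, to -0.187, and the share of higher calls from 46.8% to 31.1%. That centring shifted the median of all features by -0.0637 between the αA-labelled and parental lines and by 0.107 between the αB-labelled and parental lines.

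The differences of the labelled lines from parental cells were set against each other. Of the features called in both comparisons, 536 were higher in both (356 expected for independent lists), 910 were lower in both (549 expected) and 1803 went in opposite directions (884 expected). Across genes, which are not independent replicates, the correlation of the log2 differences was -0.036 (Spearman's rho 0.115). Simulated unchanged lines that shared the parental arrays gave a mean r of 0.386. The covariance was -0.00793 against 0.0149 in the simulation, a difference of -0.0229. With the parental arrays split so that no array was shared, r was -0.168, with 4 pairs for each line. The αB-labelled pairs were at 10 and 100, which left the αA-labelled pairs at 0.1 and 1. Those αA-labelled arrays include the ones on slide 1 and the array at 48 h and 0.1. The sets thus differed in dose and slide as well as in line, so this r does not isolate the effect of sharing parental arrays. Blocking by slide gave an r of 0.298, and the arrays at 10 and 100 alone, with shared parental arrays, gave 0.111, neither with an unchanged simulation of its own to set it against.

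The contrast of 48 h with 36 h estimates 1 time effect over the 3 lines together, which a called gene need not show in each line. BST2, of the interferon response, rose by 1.02 ± 0.08 (SE) on the log2 scale, a fold of 2.02, and the secreted hyaluronan-binding protein gene TNFAIP6 by 1.08 ± 0.10, each in 10 of 10 pairs. DCN rose by 0.96 ± 0.09 and KCNAB2, a potassium channel subunit gene, by 0.98 ± 0.08, also in 10 of 10 pairs. The reductase gene DHRS2 fell by 0.85 (-0.85 ± 0.07) and NPPB, which encodes a natriuretic peptide, fell by 0.66 (-0.66 ± 0.10), in all 10 pairs.

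Of 30 interferon response genes 10 rose and 0 fell (the same adjusted over the list alone), with IFIH1 at 0.55 ± 0.06 in 10 of 10 pairs (camera adjusted p = 3.65e-05, and adjusted p = 0.146 with an estimated correlation). Of 15 fibroblast markers 5 rose and 0 fell (6 and 0 adjusted over the list alone), with LUM at 0.51 ± 0.07 (camera adjusted p = 0.000454, and adjusted p = 0.216 with an estimated correlation). Of 10 pigment cell markers 3 rose and 0 fell (3 and 1 adjusted over the list alone), with PMEL at 0.41 ± 0.06 (camera adjusted p = 0.0248, and adjusted p = 0.228 with an estimated correlation). Of 25 heat shock and chaperone genes 2 fell, HSPH1 at -0.20 ± 0.05 and CHORDC1 at -0.27 ± 0.08 (4 adjusted over the list alone; camera adjusted p = 0.000511, and adjusted p = 0.53 with an estimated correlation). Of 24 unfolded protein response genes 3 fell (7 adjusted over the list alone), among them CHAC1, which encodes a glutathione-degrading enzyme, at -0.70 ± 0.16 (camera adjusted p = 0.000511, and adjusted p = 0.437 with an estimated correlation). CHAC1 was lower in 8 of the 10 pairs and higher in the 2 αB-labelled pairs.

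**Figure D3:**
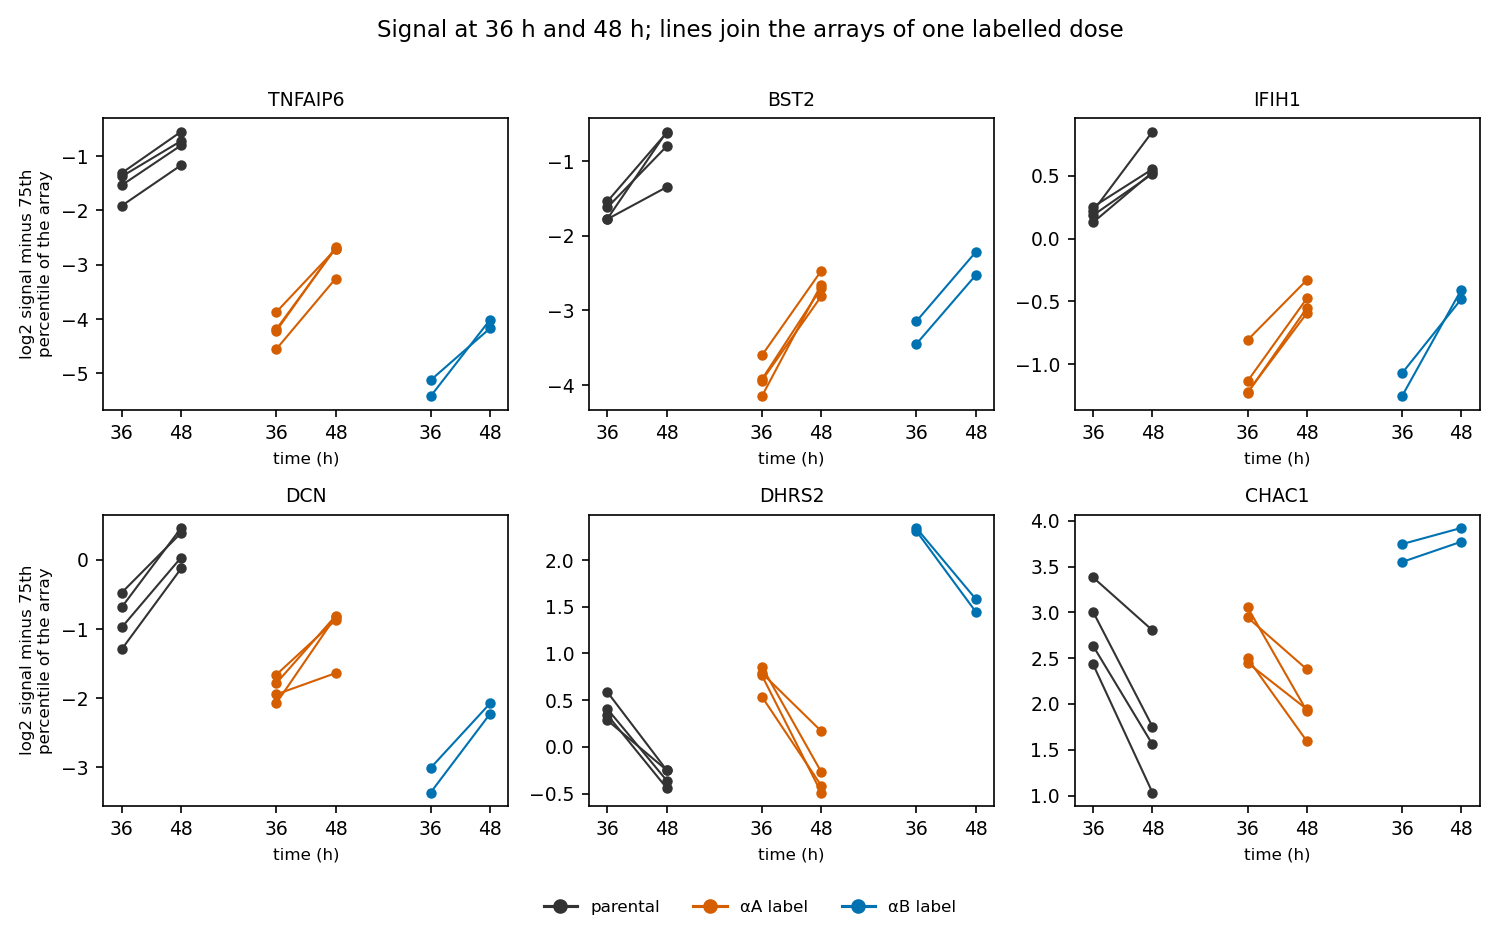
Normalised log2 signal (y axis) of 6 genes at 36 h and 48 h (x axis) in the 3 lines, with lines joining the arrays of 1 labelled dose. TNFAIP6, BST2, IFIH1 and DCN rose and DHRS2 fell in 10 of 10 pairs, while CHAC1 fell in the 8 parental and αA-labelled pairs only.

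In all, 2510 features changed between 36 h and 48 h, 1628 higher and 882 lower at 48 h, and 1165 went the same way in 10 of 10 pairs. Of these, 43 changed by at least 1 on the log2 scale, 40 of them upward. With slide as a block 1088 passed, 930 of them shared and in the same direction, with a median size ratio of 1.01, and the 5 lists kept direction and call with adjusted p between 1.56e-06 and 0.0151. Within slide 2 and slide 3 alone 0 and 3 features passed. BST2 differed by 1.30 within slide 2 and 0.99 within slide 3, and DHRS2 by -1.09 and -0.83. Centring on the array median gave 428 features and a share of higher calls of 53.5% instead of 64.9%, and array weights gave 3982 and 50.3%. TM4SF1-AS1, with the largest rise of the long noncoding RNAs named (1.33 ± 0.28), was at 0.76 with slide as a block (adjusted p = 0.38), and the chaperone genes HSPH1 and CHORDC1 did not pass either (adjusted p = 0.213 and 0.432).

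The slope over labelled dose asks which genes followed the amount of dexamethasone. Few genes passed the threshold. ANGPTL4, which encodes an inhibitor of lipoprotein lipase, rose by 0.57 ± 0.08 (SE) on the log2 scale per 10-fold dose, a fold of 1.49. CPT1A, the gate of mitochondrial fatty acid import, rose by 0.47 ± 0.07, the small GTPase gene RHOB by 0.48 ± 0.08 and the transcription factor gene KLF2 by 0.41 ± 0.09. GASK1B fell by 0.32 (-0.32 ± 0.05), EDN2, an endothelin gene, fell by 0.31 (-0.31 ± 0.05), and both kept this sign in 6 of 6 series. The naming rule required this for the largest rises and falls. Each αB-labelled series holds only the doses 10 and 100, so its slope is a single difference. In the αA-labelled arrays at 36 h, 0.1 and 1 were on slide 1 and 10 and 100 on slide 2. In the parental arrays at 48 h these doses were divided in the same way between slides 3 and 4. Of 37 glucocorticoid-induced genes 2 rose, ANGPTL4 and PDK4 (0.26 ± 0.05), and 1 fell (4 and 5 adjusted over the list alone) with a camera adjusted p of 0.741. FKBP5, a standard glucocorticoid-induced gene, had a slope of -0.13 ± 0.03 (adjusted p = 0.0669), TSC22D3 0.08 ± 0.04 (0.215), PER1 -0.01 ± 0.03 (0.945) and ZBTB16 0.02 ± 0.04 (0.852). The receptor gene NR3C1 had a slope of 0.01 ± 0.03 (0.879).

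Of 24 immediate early genes 2 rose with dose, KLF2 and NR4A3 (3 adjusted over the list alone; camera adjusted p = 0.0016, and adjusted p = 0.437 with an estimated correlation). The median slope of these genes was -0.04 within slide 2 and 0.08 within slide 3, so its direction turned. The 24 unfolded protein response genes had a median slope of 0.04 with 0 called (3 adjusted over the list alone; camera adjusted p = 0.00414, and adjusted p = 0.54 with an estimated correlation), and the 25 cholesterol biosynthesis genes 0.04 with 0 called (camera adjusted p = 0.00451, and adjusted p = 0.651 with an estimated correlation). Of 15 fibroblast markers 1 fell, LUM at -0.20 ± 0.03 (5 adjusted over the list alone; camera adjusted p = 0.0296, adjusted p = 0.53 with an estimated correlation, and adjusted p = 0.149 with slide as a block).

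**Figure D4:**
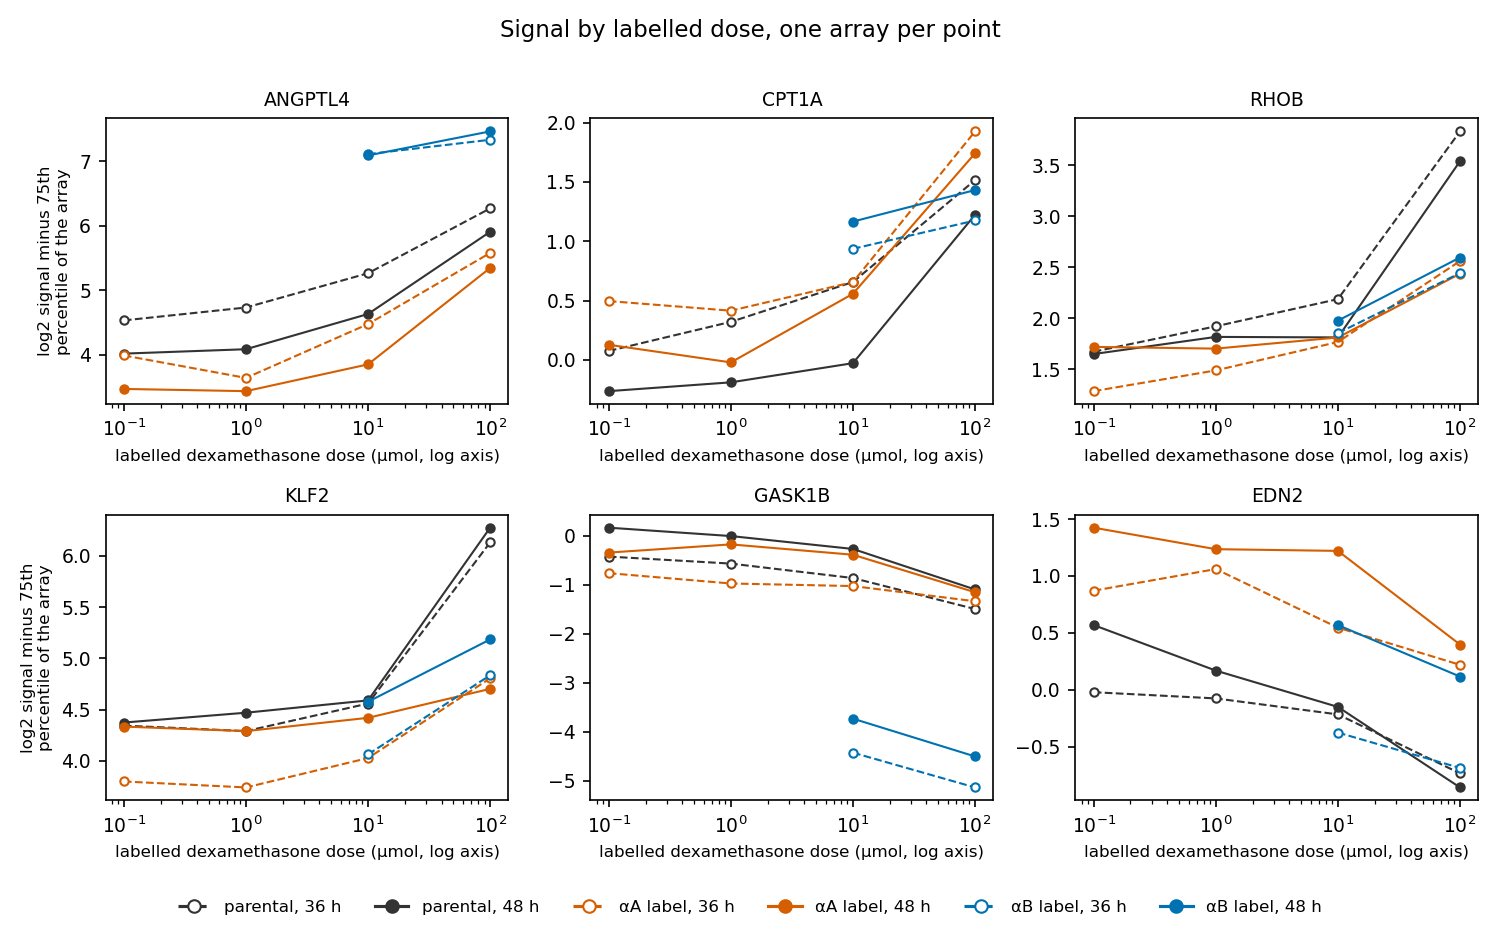
Normalised log2 signal (y axis) of 6 genes against labelled dexamethasone dose (x axis, log scale) in the 3 lines at 36 h (open symbols, dashed lines) and 48 h (filled symbols, solid lines), with 1 array per point. ANGPTL4, CPT1A, RHOB and KLF2 had positive slopes and GASK1B and EDN2 negative slopes in 6 of 6 series of 1 line and 1 time. Each αB-labelled series holds only the doses 10 and 100.

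In all, 189 features changed with dose, 56 upward and 133 downward, 118 of them with the same sign in 6 of 6 series, and none by as much as 1 on the log2 scale per 10-fold dose. This count moved with single arrays: 0 passed without the αA-labelled or without the parental array at 48 h and 100, and 587 without the αA-labelled array at 48 h and 10. It was 357 without the αA-labelled array at 48 h and 0.1, 78 without the αA-labelled and 39 without the parental array at 36 h and 100. It was 125 without the αB-labelled array at 48 h and 100, 117 without the parental array at 36 h and 0.1, and 82 and 111 without the parental arrays at 48 h and 0.1 or 1. With slide as a block 3 features passed, none of the 189, although all 189 kept their sign at a median size ratio of 0.964. ANGPTL4 then had a slope of 0.56 (adjusted p = 0.0954) and CPT1A of 0.50 (0.0954), while within slides 2 and 3 ANGPTL4 had slopes of 0.61 and 0.51, with 0 features passing in either. Centring on the array median left 11 features, 81.8% of them upward, against 29.6% of the 189. The share was 47.1% of 420 with quantile normalisation, 48.5% of 1129 with normexp correction and 47.6% of 418 in the deposited log2 table.

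Whether time and dose effects differed between lines was tested with interaction terms. For the time effect of the αA-labelled against the parental line limma called 0 features, with 5784 at an unadjusted p under the threshold. For the dose slope of these lines it called 115 features, of which 111 had a lower slope in the αA-labelled line, among them the p53 family gene TP73 at -0.57 ± 0.08 (adjusted p = 0.046). For the αB-labelled line it called 828 features by time, 431 with a higher effect, and 2 by dose, lnc-BTNL8-2 at 2.44 and the transcript ENST00000276974 at -0.85 (each adjusted p = 0.0325). Of the features with a gene symbol and above background on all 20 arrays, the 6 with the smallest p were as follows. NUPR1, PSAT1, SLC7A11, ASNS and H4C4 had time effects higher by 2.04, 1.89, 1.73, 1.75 and 1.25 in the αB-labelled line than in parental cells, and NRBP2 had one lower (-1.29). No gene list was tested on these terms. These genes, TP73 and the 2 features named for dose were chosen after their values were seen. For the αB-labelled line, time and slide cannot be told apart. Dose also ran partly with slide in the αA-labelled and parental lines. In a fit with slide as a block, chosen after seeing the data, limma called 0 of the 115 dose slopes of the αA-labelled line, with 2430 features at an unadjusted p under the threshold. All 115 kept their sign there at a median size ratio of 0.870, and the median SE over all features rose from 0.0858 to 0.0991. That fit called 0 time effects of the αA-labelled line, with 1643 at an unadjusted p under the threshold, and 1 of the 2 dose slopes of the αB-labelled line.

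All 4 interaction counts moved with single arrays. The time count of the αA-labelled line was 2434 without its array at 48 h and 100, 143 without that at 36 h and 10 and 1 without that at 36 h and 1. Its dose count was 2324 and 668 without its arrays at 48 h and 100 or 1, and 26, 7 and 12 without those at 36 h and 10, 36 h and 100, and 48 h and 10. That count was 5 and 1 without the parental arrays at 36 h and 100 and at 48 h and 0.1, and 0 without any other array. For the αB-labelled line the time count was 32 without either array at the labelled dose of 10 and 62 without either at 100. It was 469, 398 and 339 without the parental arrays at 36 h and 1, 10 or 100, and 427 and 420 without those at 48 h and 10 or 100. The dose count was 10 without either αB-labelled array at 36 h, 11 without either at 48 h, 1 without the parental array at 36 h and 0.1, and 0 without any other.

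Without a slide term, the remaining lists were called in none of the 5 comparisons. Over the 5 comparisons the smallest camera adjusted p was 0.203 for glucocorticoid-induced genes (48 h against 36 h), 0.138 for crystallins and 0.138 for endothelial markers (αB-labelled against parental), and 0.217 for lens fibre genes (48 h). It was 0.29 for lens epithelium genes (αA-labelled against αB-labelled) and 0.124 for p53 targets and apoptosis (αA-labelled against parental and dose). For glycolysis and hypoxia it was 0.178 (48 h, median -0.05), but 0.0029 with slide as a block (median -0.10), which changes the call. For well-known long noncoding RNAs it was 0.175 (αB-labelled against parental) and for keratinised epithelium markers 0.43 (48 h), and for neuron markers 0.295 (48 h). Of the 37 glucocorticoid-induced genes, 8 were higher and 11 lower in the αA-labelled and 6 higher and 8 lower in the αB-labelled line than in parental cells. NR3C1 differed by -0.28 ± 0.07 in the αA-labelled line (adjusted p = 0.0041) and by 0.06 with slide as a block, and FKBP5 by 0.36 ± 0.08 and by -0.10 with the block, so that the sign of both depended on how slide was treated.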

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

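The tests of CRYAA and CRYAB, of the slide and single-array effects on the dose slope, of negative control spots, of brighter and dimmer probes on other arrays and of the dose split with the most calls were chosen after the results were seen, whereas the other splits of the arrays and the 2 other tests of the array at 48 h and 0.1 were planned before.

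CRYAA was high in the αB-labelled arrays, against the labels, and CRYAB was highest in the αA-labelled arrays by a smaller difference. At A_33_P3323559, with the smaller difference of the 2 CRYAA probes above background in the αB-labelled line, that line exceeded parental cells by 1.20 (0.18 at the other probe, which is below background in both), and for CRYAB the αA-labelled line exceeded them by 0.600, both of which an exchange of the 2 labels needs. A slide or background effect as the whole source is argued against within slide 2, where the labelled lines differed in CRYAA by -1.59 at A_33_P3323559. At A_23_P132147 the slide 2 means were -7.46 in the αA-labelled and -0.12 in the αB-labelled line. The αA-labelled arrays also stood apart by slide at A_33_P3323559, at a mean of 0.02 on slide 1 and -1.25 on slide 2, so the size there is uncertain. An exchange of the labels may therefore explain the pattern, although lines in which the constructs acted otherwise than named, or coding sequences that the CRYAA probes do not match, were not tested. No biological explanation was tested.

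Dose slopes were called for 189 features without and for 3 with slide as a block, and none were shared. The median size ratio was 0.964, while the median SE rose from 0.0365 to 0.0446 and fewer degrees of freedom were left. In the blocked fit 3461 features differed between slides 2 and 1, 272 between slides 3 and 2 and 123 between slides 4 and 3. The ratio covers features picked for their slopes on these arrays, and line and slide explained 0.353 of the dose variance. Chance slopes would largely carry over as well, so the ratio cannot tell how far slide differences contributed. The αA-labelled array at 48 h and 0.1 alone as the source is argued against, since 166 of the 189 were also called in the same direction without it. However, 0 passed without the αA-labelled or without the parental array at 48 h and 100. Of 100 splits 2 gave at least as many calls, the real one included (189 against a highest other of 288). The doses of the split with 288 had a correlation of -0.0744 with the real ones and 0.270 of their variance explained by line and slide, against 0.353. So many calls were rare among these splits, which ignore slide. A dose order unrelated to the real one still gave more, so the count does not exclude chance. A response to dexamethasone stays open as the biological explanation and was not tested against an untreated array.

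The αA-labelled array at 48 h and 0.1 had 48295 probes above background, against 35422 to 38353 on the other arrays of the line. A change in abundant genes is argued against, since the SD of its difference to the other arrays of its line and time was 0.243 over the brighter probes, within the 0.169 to 0.378 of 15 other αA-labelled and parental arrays, and 1.11 over the dimmer (0.487 to 0.690), a ratio of 0.219 (0.338 to 0.652, some under the bound of 0.5 used at first). A broad added signal may explain it. The array detected 45.6% of 15340 probes that no other array detects, against at most 1.30% on any other array, but this largely restates its higher count. The share was similar for protein-coding (44.5%) and long noncoding names (46.7%). Nonspecific hybridisation or scanner background may be its source, since the negative control median was 28.1 against 23.1 to 24.6 on the other arrays of its slide, although it was 26.8 and 27.7 on slide 1. The median local background around these spots was 30, within the 30 to 32 of the other arrays of its slide. No raised background around the spots was thus seen. Marker lists of 6 other cell types were higher there by medians of 0.107 to 0.570, and no biological explanation was tested.

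Other arrays stood apart from their group by the gap to the nearest array. The αB-labelled array at 36 h and 10 had 35996 probes above background against 35260 to 35380. In the αA-labelled line lnc-PKN2-2 was at -5.24 at 48 h and 0.1 (others -4.75 to -4.40), COL3A1 at -0.63 at 36 h and 100 (0.07 to 0.62) and lnc-TMEM135-2 at -4.50 at 48 h and 100 (-3.53 to -2.95). In the αB-labelled line at 48 h and 10, CCNE1 was at 2.50 (2.63 to 2.65) and NUSAP1 at 5.74 (5.61 to 5.62). In the parental line at 48 h and 100, MITF was at -0.90 (-1.19 to -1.07) and lnc-FAM27D1.1-3 at -4.01 (-3.53 to -3.15). With the array of the paragraph before, these were 9 of 255 groups tested, where chance gives about 1 in 20, or 12.75.

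Effects that differed between lines by an interaction term were the 115 dose slopes of the αA-labelled line, and 828 time effects and 2 dose slopes of the αB-labelled line. The time effect of CHAC1 differed by 1.28 (limma adjusted p = 0.026) between the αB-labelled and parental lines. HOXA3 was called too, at -0.78 (limma adjusted p = 0.0125). It was below background on all 4 αB-labelled arrays, so that this is no measured difference.

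Among 100 splits of the arrays chance was excluded for the αA-labelled against the parental line (10170 real calls, highest other 5173, with 1 split as large), the αB-labelled against the parental line (5366 and 2, 1) and the labelled lines against each other (9692 and 4102, 1). It was also excluded for time (2510 and 25, 1) and for the dose interaction of the αA-labelled line (115 and 5, 1). This holds only for splits that ignore slide. Those 115 were 0 with slide as a block and 0 with quantile, normexp, array median or deposited values. They were 0 to 2324 when 1 array was left out. For the time interaction of the αB-labelled line no other split gave as many calls (828 and 73, 1). That line had only 2 arrays at each time, which allow few distinct splits by time. The comparison therefore cannot exclude chance for that interaction. Chance was not excluded for the dose interaction of the αB-labelled line (2 and 7, 36). For the time interaction of the αA-labelled line limma called 0 features, with 5784 at an unadjusted p under 0.05, so that all 100 splits were as large by construction (highest other 1) and the comparison says nothing about chance. These splits ignore slide, and why some of those between lines gave many calls was not tested.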

How the results depend on the processing

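The slide-1 and single-slide alternatives, and slide as a fixed block for the crystallin probes, the gene lists, the interactions and the correlation of line differences, were chosen after seeing the data, and the other alternatives before the data were examined. Signal over background limits the results to 30505 features, and folds against lines below background are lower bounds. A setting that leaves 1 array in an arm assumes that the lone array varies like the other groups. Over 154 results for named genes and 42 settings, 5201 values kept direction and side of the threshold, 314 fell below it, 44 passed it, 69 moved and 3 reversed. The reversed ones were FKBP5 between the labelled lines with the mean of its probes (-0.0779 instead of 0.28), and FKBP5 (-0.0977 instead of 0.36) and NR3C1 (0.0569 instead of -0.28) between the αA-labelled and parental lines with slide as a block. Except where fewer arrays or a slide term leave fewer degrees of freedom, the cause was not tested.

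The 189 dose calls were 420 with quantile normalisation, 1129 with normexp, 11 with the array median, 418 in the deposited table, 76 without a filter and 426 over features above background on all 20 arrays. They were 1184 with array weights, 105 with dose as 4 levels, 629 with slide as a random and 3 as a fixed block, 787 with series as a block and 0 from doses 10 and 100 alone. Without the slide 1 arrays they were 362, without these and the αA-labelled array at 48 h and 0.1 they were 1023, and within slides 2 and 3 they were 0 and 0. Leaving out 1 array gave 0 to 587.

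For the αA-labelled line the 0 time interactions were 1 with quantile normalisation, 3 with the array median, 1 in the deposited table, 1 without a filter and 6733 with array weights (0 to 2434 leaving out 1 array). Its 115 dose interactions were 0 with quantile, normexp, array median, the deposited table and slide as a fixed block, 1 without a filter, 61 over features on all 20 arrays and 4572 with weights (0 to 2324). For the αB-labelled line the 828 time interactions were 1387 with normexp, 178 with the array median, 303 without a filter and 3342 with weights (32 to 1173). Its 2 dose interactions were 0 with quantile, normexp, array median, the deposited table, no filter and features on all 20 arrays, 1 with slide as a fixed block and 9 with weights (0 to 11).

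Counts of αA-labelled against parental were 5306 with slide as a random and 1267 as a fixed block and 5839 at 48 h alone (9118 to 10312 leaving out 1 array). For αB-labelled against parental they were 2912 with the array median, 2873 with slide as a fixed block, 2554 with matched conditions as a block, 3237 at 48 h alone and 1492 within slide 3 (4158 to 5668). Between the labelled lines they were 6429 with matched conditions as a block, 6266 at 36 h alone and 3647 within slide 2 (8343 to 9975). For time they were 428 with the array median, 3982 with weights, 1088 with slide as a fixed block and 0 and 3 within slides 2 and 3 (1972 to 2684). List calls numbered 23, 0 with an estimated correlation and 26 with slide as a block, of which 21 were shared. The 5 called only with the block were cholesterol biosynthesis in the αA-labelled and αB-labelled against the parental line, glycolysis and hypoxia with time, and inflammatory and interferon genes with dose.

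CRYAA at A_23_P132147 was -0.0388 between the αA-labelled and parental lines with quantile normalisation, but the probe was above background on 1 and 0 arrays of these lines, so that this is no measured difference. CRYAB between the αB-labelled and parental lines was 0.158 with quantile normalisation and 0.160 with normexp. Between the αA-labelled and parental lines it was 0.544 with slide as a fixed block, and between the labelled lines 0.375 within slide 2. The correlation of line differences was 0.000408 with quantile normalisation and 0.298 with slide as a block.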

Other observations

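All of the tests in this part were chosen after the values were seen, and the families below were 14 looked at in 5 comparisons, with p adjusted over 70 tests. The αB-labelled line had lower signal of many HOXA, HOXC and HLA genes than parental cells. Of 9 HOXA homeobox genes 7 were lower (median -1.44, -1.18 with slide as a block; camera adjusted p = 6.53e-09, and adjusted p = 0.000573 with an estimated correlation), with HOXA5 at -1.47 in that line and at 1.29 in the αA-labelled line. Of 7 HOXC genes 4 were lower, with HOXC6 at -2.38 (median -0.83, -1.31 with slide as a block; adjusted p = 0.00145 with an estimated correlation). Of 9 HOXB genes 1 was lower and 1 higher (adjusted p = 0.824 with an estimated correlation), and of 3 HOXD genes 1 was lower (adjusted p = 0.0517 with an estimated correlation). Of 21 HLA genes, whose products present peptides to T cells and whose near-identical members share signal, 11 were lower, with HLA-B at -1.12 (median -0.82, -0.58 with slide as a block; adjusted p = 0.000336 with an estimated correlation). Pregnancy-specific glycoprotein genes were higher, 7 of 8, with PSG1 at 1.93 (median 1.42, 1.31 with slide as a block; adjusted p = 0.0317 with an estimated correlation).

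In the αA-labelled line 9 of 11 genes of immune proteasome subunits and antigen transport were lower than in parental cells (median -0.93, -0.81 with slide as a block; adjusted p = 0.000942 with an estimated correlation), as were 8 of 11 in the αB-labelled line (median -0.46, -0.42 with slide as a block; adjusted p = 0.00272 with an estimated correlation). Of 9 HOXA genes 7 were higher in the αA-labelled line and 1 was lower (median 0.73, 0.55 with 1 member at its bound, 0.33 with slide as a block; adjusted p = 0.00366 with an estimated correlation). Between 36 h and 48 h, 8 of 21 HLA genes rose (median 0.14, 0.18 with slide as a block; adjusted p = 0.00272 with an estimated correlation). Of 22 genes of amino acid synthesis and transfer RNA synthetases 10 fell, with the cystine transporter gene SLC7A11 at -1.05 and the serine synthesis gene PSAT1 at -0.74 (median -0.26, -0.43 with slide as a block; adjusted p = 0.0735 with an estimated correlation). The directions of these medians were the same under the 5 scalings tried, but normexp with quantile normalisation made several smaller. In the αB-labelled line it gave -0.40 for HOXA, -0.31 for HOXC, -0.24 for HLA and 0.86 for pregnancy-specific glycoprotein genes, and in the αA-labelled line 0.32 for HOXA genes. Centring on the array median gave 0.07 for the rise of HLA genes with time. Time and slide cannot be told apart in the αB-labelled line, where SLC7A11 and PSAT1 had higher time effects than in parental cells.

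ANGPTL4, CPT1A, PDK4 and SLC25A20 rose with dose, and these are targets of the fatty acid sensing receptors PPARα and PPARδ. The hypothesis that PPAR target and fatty acid oxidation genes rise with dose was tested on 28 further genes of a list written after these 4 were seen. Their median slope was 0.03 (0.0316) per 10-fold dose, 19 of 28 slopes were positive and 1 gene, ACADVL, was called (3 up and 1 down adjusted over the list alone). The camera p was 0.00869, and 0.136 with an estimated correlation. With slide as a block the median over the 28 genes was 0.0157 (camera p = 0.0138 at the preset correlation). The small shift is consistent with a weak rise of the group, found and tested on the same arrays, and does not reach the threshold when correlation between genes is estimated.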
